A study of Homo sapiens with 9 samples.

How the data were processed

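Gene expression was measured by RNA sequencing in Ramos cells, with 3 biological replicates each at 0 h (untreated), 3 h and 6 h in 3 µM CHIR99021. The authors deposited raw read counts per Ensembl gene, and the values were whole numbers whose totals differed between libraries. Per the submitters' processing notes, reads were aligned with GSNAP 2015-12-31 to build hg19 and counted with HTSeq 0.6.0. Those notes also list limma 3.30.0, but the deposited counts were not normalised. The annotation release, the strand setting and the counting mode were not given in the sources used here, so antisense and overlapping genes are uncertain.

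The table held 60234 gene identifiers and 5 HTSeq summary entries, which were set aside before any test. The share of reads in genes was 67.6% to 70.9%, without a feature 15.0% to 17.6%, ambiguous 2.53% to 2.76%, and not uniquely aligned 9.90% to 11.7%. Low quality alignments took 0.418% to 0.513% and unaligned reads 0.329% to 0.458%. Reads in genes numbered 46359911 to 52880876 per library, at which a count of 0 allows up to 0.0567 to 0.0647 CPM. Transcript lengths and GC contents came from GENCODE v29 (GRCh38), matched by gene identifier. Symbols came from a separate gene name reference, also matched by identifier, and 39539 identifiers had a symbol. Of the gene list entries, 9 had no match and are not analysed here.

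Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15847 of 28412 with any count. Libraries were scaled by TMM factors, with means of 1.11, 0.962 and 0.940 at 0 h, 3 h and 6 h. A robust quasi-likelihood model with a mean per group was fitted to all 9 libraries, with 6 residual degrees of freedom. The tests compared 3 h with 0 h, 6 h with 0 h and 6 h with 3 h, and an F test asked for any difference among the 3 times. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic.

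The 29 gene lists comprised beta-catenin/TCF targets, MYC-activated genes of ribosome biogenesis and of metabolism and translation, MYC-repressed genes, the MYC network, GSK-3 pathway components, extrinsic apoptosis, the BCL2 family, and p53, NF-kappaB, immediate early, ATF4, SREBP, NRF2 and FOXO target genes. They also comprised G1/S, G2 and mitosis, germinal centre B cell, plasma cell, glycolysis and hypoxia, heat shock, interferon and lysosome genes, markers of T and NK, myeloid, and epithelial and fibroblast cells, mitochondrial RNA, ribosomal proteins and replication histones. The 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry. Members were also counted after adjusting over the list alone. Some genes belong to more than 1 list, so the lists are not independent.

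The design, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named a fixed set of MYC, GSK-3 and apoptosis genes whatever their values, and up to 4 members of each list per comparison with the smallest p. It also named the 8 genes of each direction against 0 h and the 5 between 3 h and 6 h with the largest change among genes with a symbol, a mean of at least 1 CPM, an adjusted p under 0.05 and no overlap between libraries. The text gives a part of these, and some genes that the rule named are not reported here. A class for changes that went further in the same direction between 3 h and 6 h was added to the fixed time classes, and 1679 genes that passed in a comparison fell in no class.

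The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors, upper-quartile factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, the compared groups alone, a minimum fold of 1.2, an adjusted p under 0.01 for the time classes, and leaving out each library in turn. Removal of GC and length trends per library was added after seeing the data. Simulated data sets with no effect, 100 in number, in which both comparisons used the same simulated untreated libraries, gave the correlation and the shared genes that shared controls alone produce. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

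The procedure was tested on simulated data with 50 genes changed at each fold, far fewer than passed in the real comparisons. With so few, the adjusted threshold calls for smaller p-values, so the recovered shares do not carry over to the real data. For 3 h against 0 h, it recovered 14% of genes at 1.2-fold, 66% at 1.5-fold, 88% at 2-fold and 100% at 4-fold. Of the genes it called, 6.29% were unchanged, against 9.21% for 6 h against 0 h and 11% for 6 h against 3 h, which is above the nominal 5%. Of 100 simulated lists of 25 genes, 10 of 10 shifted by 1.5-fold and 0 of 90 unshifted lists were called by camera at the preset correlation. The simulated genes were drawn independently, so this leaves out correlation between the genes of a list. In the real lists the correlation estimated at 3 h ran from -0.0127 (BCL2 family) to 0.883 (ribosomal proteins), so the simulation does not show how often the preset calls correlated lists wrongly.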

Results

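RNA was sequenced from Ramos cells, an EBV-negative Burkitt lymphoma B cell line in which MYC is driven by an immunoglobulin locus. The cells were untreated (0 h) or kept for 3 h or 6 h in 3 µM CHIR99021, a small molecule inhibitor of both forms of the kinase GSK-3. GSK-3 marks MYC and beta-catenin for degradation, and the series concerns MYC stabilization and extrinsic apoptosis in B cell lymphoma. Each time had 3 biological replicates, which gave 9 libraries. Between 46359911 and 52880876 reads per library lay in genes, and 15847 genes had enough reads to be tested. No library came from untreated cells kept for 3 h or 6 h, so treatment and time in the treated culture went together. Levels are normalised read counts scaled to library size (CPM), given as the mean ± SD of 3 libraries, and log2 fold changes carry their standard error (SE). A log2 fold change of 1 is a doubling. MYC protein was not measured here.

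The 3 times separated on the leading principal components of log2 CPM, which held 68.6% and 14.9% of the variance. The biological coefficient of variation within groups was 6.53%. Replicates differed beyond sampling noise in each group. The closest pair was untreated replicates 1 and 2, with a chi-square of 1.74 per degree of freedom, against 32.5 and 29.1 for replicate 3 against them. In the treated groups this ratio ran from 2.65 to 13.3. The test covers counting error alone, so it argues against a repeated deposit of 1 library and does not show that the libraries were independent. All 9 were counted as biological replicates because the series describes them so. Across the 3 times, 12319 genes (77.7% of those tested) differed at an adjusted p under 0.05 in the edgeR F test.

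**Figure D1:**
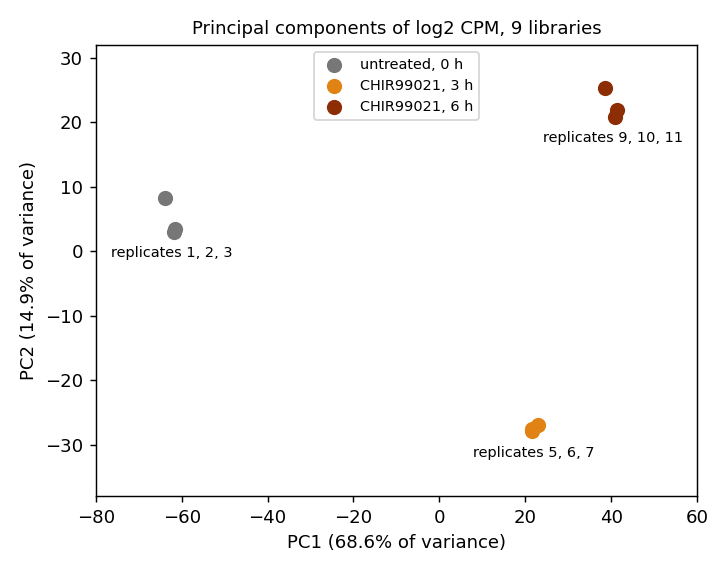
Scores of the 9 libraries on the first (x axis, 68.6% of variance) and second (y axis, 14.9%) principal components of log2 CPM, in the units of the scores. Each point is a library and its colour is the time, and each group of 3 replicates lies apart from the others.

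At 3 h, MYC mRNA was lower while genes that MYC is known to activate in ribosome biogenesis were higher. MYC (ENSG00000136997) fell from 558 ± 22.6 CPM to 447 ± 22.2 CPM, a log2 fold change of -0.32 (SE 0.052, edgeR adjusted p = 9.36e-05), and did not pass against a minimum fold of 1.2 (adjusted p = 0.0991). All 29 measured ribosome biogenesis genes rose, by a median of 1.28 on the log2 scale (2.43-fold; camera adjusted p = 8.15e-33, but adjusted p = 0.0684 with an estimated correlation). Among them were NCL (ENSG00000115053), the nucleolar protein nucleolin, with a log2 fold change of 1.43 (SE 0.048), the nucleolar proteins NOP56 (1.61, SE 0.043) and NOP2 (1.56, SE 0.043), and RRP12 (1.93, SE 0.06). Of 31 MYC-activated genes of metabolism and translation, 25 rose and 1 fell, with a median of 0.45 (camera adjusted p = 3.69e-06; adjusted p = 0.287 with an estimated correlation). EIF4G1, a translation initiation scaffold, rose 2.54-fold, the transferrin receptor TFRC 2.70-fold and ODC1, the first enzyme of polyamine synthesis, 1.68-fold.

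Genes known to be repressed by MYC moved mostly the other way at 3 h. Of 13 measured, 9 fell and 1 rose, with a median of -0.73 (camera adjusted p = 0.0166; adjusted p = 0.287 with an estimated correlation). CDKN1B, an inhibitor of cyclin-dependent kinases, fell 2.29-fold, GADD45A, a growth arrest gene, 2.65-fold and the transcription factor KLF6 1.66-fold. CDKN1B and KLF6 are also in the list of FOXO targets, so the falls of these lists are not independent. The MYC-repressed gene that rose was CDKN1A (ENSG00000124762), also a kinase inhibitor, from 1.00 ± 0.0841 to 9.80 ± 0.303 CPM, a log2 fold change of 3.29 (SE 0.1, edgeR adjusted p = 1.97e-11). In the list of MYC, its partners, competitors and stability regulators, 8 of 19 rose and 8 fell, and the list did not pass (camera adjusted p = 0.726). MAX, the partner of MYC, rose 1.32-fold and the deubiquitinase USP36 3.18-fold, whereas the MAX-binding competitors MXI1 and MXD3 fell 3.02-fold and 2.95-fold. FBXW7, which targets MYC for degradation, rose 1.30-fold.

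Beta-catenin/TCF targets divided at 3 h: of 19 measured, 6 rose, 5 fell and 8 did not pass. AXIN2 (ENSG00000168646), a feedback inhibitor of the pathway, rose from 1.99 ± 0.247 to 3.99 ± 0.300 CPM (log2 fold change 1.01, SE 0.11, edgeR adjusted p = 2.07e-06). The transcription factor TCF7, the ubiquitin ligase ZNRF3 and the kinase SGK1 rose 1.64-fold, 1.69-fold and 4.59-fold, from 0.760, 12.3 and 0.846 CPM. LEF1 fell 1.16-fold from 205 CPM and the adhesion receptor CD44 2.35-fold from 2.37 CPM. The list did not pass (camera adjusted p = 0.953), and its median of -0.20 and mean of -0.02 had the opposite sign to its test. Of 20 pathway components, 8 rose and 7 fell (camera adjusted p = 0.953). CTNNB1, which encodes beta-catenin, rose 1.27-fold and GSK3A 1.24-fold, the latter with an adjusted p of 0.126 under scaling by library size alone. GSK3B had a log2 fold change of 0.14 (SE 0.071, edgeR adjusted p = 0.0928), which passed without untreated replicate 2 (adjusted p = 0.0356) and with no filter (0.0361).

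Genes of extrinsic apoptosis moved in both directions at 3 h, with 9 of 25 higher, 11 lower and 5 not passing (10 higher and 11 lower when adjusted over the list alone; camera adjusted p = 0.953). The TRAIL receptor TNFRSF10A (ENSG00000104689) rose from 47.8 ± 1.96 to 72.8 ± 1.17 CPM (log2 fold change 0.61, SE 0.049, edgeR adjusted p = 9.07e-08). The other signalling TRAIL receptor, TNFRSF10B (ENSG00000120889), fell from 56.3 ± 2.70 to 39.2 ± 1.17 CPM (log2 fold change -0.52, SE 0.054, edgeR adjusted p = 1.18e-06). The TNF receptor TNFRSF1A fell 4.92-fold, FAS 2.61-fold and CFLAR, an inhibitor of caspase-8 activation, 1.55-fold. The TRAIL decoy receptor TNFRSF10D rose 2.00-fold, the kinase RIPK1 2.74-fold and the caspase inhibitor XIAP 1.94-fold. CASP8 had a log2 fold change of 0.14 (SE 0.06, adjusted p = 0.061), which passed without untreated replicate 3 (adjusted p = 0.00578). Of 17 BCL2 family and intrinsic apoptosis genes, 3 rose and 9 fell (camera adjusted p = 0.072, and 0.046 both without untreated replicate 1 and with scaling by library size alone). BBC3, the BH3-only protein PUMA, fell from 14.5 ± 1.65 to 0.904 ± 0.259 CPM (log2 fold change -4.00, SE 0.173, edgeR adjusted p = 5.32e-10). The anti-apoptotic BCL2 fell 4.16-fold, from a low 1.74 ± 0.294 to 0.416 ± 0.0645 CPM, and APAF1, the apoptosome scaffold, 2.30-fold. The BH3-only BCL2L11 rose 1.91-fold, the anti-apoptotic MCL1 1.33-fold and cytochrome c (CYCS) 1.68-fold.

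Sterol synthesis and heat shock genes were higher at 3 h. Of 28 SREBP targets of sterol and fatty acid synthesis, 24 rose and 1 fell (25 and 1 when adjusted over the list alone), with a median of 0.99 (1.99-fold; camera adjusted p = 2.36e-17; adjusted p = 0.0684 with an estimated correlation). HMGCS1 (ENSG00000112972), which makes HMG-CoA, rose from 393 ± 27.3 to 1237 ± 45 CPM (log2 fold change 1.66, SE 0.058, edgeR adjusted p = 5.01e-11). SQLE, a sterol enzyme, rose 2.65-fold, and INSIG1, a sterol sensor of the pathway, 2.03-fold. Of 15 heat shock genes, 13 rose and 1 fell, with a median of 0.80 (camera adjusted p = 2.49e-13; adjusted p = 0.0684 with an estimated correlation). The chaperone HSPA8 (ENSG00000109971) rose from 289 ± 3.58 to 1893 ± 25.1 CPM (log2 fold change 2.71, SE 0.048, edgeR adjusted p = 2.78e-13), and its co-chaperones DNAJA1 and DNAJB1 rose 4.93-fold and 3.57-fold. HSPA1A and HSPA1B are near-identical copies whose reads cannot be assigned with certainty, and HSPA8 shares sequence with 17 annotated pseudogenes in the count table, so their separate values are uncertain. HSPA8P7, one of these, rose 7.00-fold.

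Of 24 genes of the G1/S transition and replication, 19 rose and 1 fell at 3 h (camera adjusted p = 0.000205; adjusted p = 0.392 with an estimated correlation). The replication licensing factor CDC6 rose 2.47-fold, the flap endonuclease FEN1 2.17-fold and the histone mRNA-binding protein SLBP 2.14-fold. Genes of G2 and mitosis did not pass as a list, with 9 of 25 higher and 6 lower (8 and 6 when adjusted over the list alone; camera adjusted p = 0.953). Of 26 ATF4 targets of the integrated stress response, 16 fell and 6 rose (camera adjusted p = 0.00457; adjusted p = 0.393 with an estimated correlation). The transcription factor ATF3 fell 3.01-fold, SESN2 1.99-fold and the mitochondrial enzyme PCK2 1.90-fold, while HERPUD1, of endoplasmic reticulum quality control, rose 2.61-fold. Of 14 plasma cell genes, 7 rose and 4 fell (camera adjusted p = 0.0439; adjusted p = 0.287 with an estimated correlation), and the list did not pass without untreated replicate 2 (adjusted p = 0.0516). HSP90B1, the endoplasmic reticulum chaperone GRP94, rose 4.03-fold and the prolyl isomerase FKBP11 2.68-fold.

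Of 29 genes of germinal centre B cell identity, 13 fell and 6 rose at 3 h. BCL6, the germinal centre repressor, fell 1.68-fold and the transcription factor MEF2B 2.18-fold, while MS4A1, which encodes CD20, rose 1.49-fold. The camera adjusted p was 0.0479 for this list, for 19 NF-kappaB targets (12 fell, 5 rose; 13 and 5 when adjusted over the list alone) and for 13 FOXO targets (9 fell, 2 rose). It was 0.287, 0.393 and 0.499 respectively with an estimated correlation. The B cell list did not pass without untreated replicate 2 (0.0516), treated replicates 6 or 7 of 3 h (0.0672 and 0.052) or any of the 6 h replicates (0.053 to 0.0624). The NF-kappaB list did not pass without untreated replicate 2, 3 h replicates 6 or 7, or 6 h replicates 10 or 11 (0.0516 to 0.0624), and the FOXO list passed only without untreated replicate 3 (0.052 to 0.085 in the other 8 fits). With the GC and length trends removed, an alternative chosen after seeing the data, the plasma cell, NF-kappaB and B cell lists did not pass (0.0585, 0.0685 and 0.0855), with medians of 0.13, -0.53 and -0.10 against 0.22, -0.49 and -0.12 before. Among NF-kappaB targets, BCL3 fell 4.17-fold and CD40 1.92-fold, while CD83 rose 1.99-fold, and among FOXO targets CCNG2 fell 1.75-fold.

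The remaining lists did not pass at 3 h. Of 21 p53 targets, 13 fell and 7 rose (camera adjusted p = 0.488), with MDM2, the p53 ubiquitin ligase, 1.48-fold higher and TP53INP1 2.87-fold lower. Of 21 immediate early genes, 7 rose and 8 fell (9 when adjusted over the list alone; adjusted p = 0.99), with the transcription factor SRF 2.03-fold higher and the phosphatase DUSP5 12.1-fold higher from 0.0772 ± 0.0269 CPM, close to the level that a count of 0 allows. Higher and lower counts were 6 and 3 of 17 NRF2 targets (5 and 3 when adjusted over the list alone; adjusted p = 0.579), 15 and 13 of 29 glycolysis and hypoxia genes (0.953), 2 and 7 of 13 interferon genes (0.488), and 9 and 9 of 26 lysosome genes (0.953). They were 2 and 1 of 13 mitochondrial RNAs (2 and 0 when adjusted over the list alone; 0.953), 1 and 1 of 30 ribosomal proteins (0 and 0; 0.953) and 0 and 7 of 14 replication histones (0.211). List median and test differed in sign for the MYC network (0.02), lysosome (0.02), ribosomal protein (0.01) and mitochondrial (-0.02) lists, and mean and median for the glycolysis (-0.05 and 0.13) and GSK-3 pathway (-0.01 and 0.08) lists. With scaling by library size alone the medians of the MYC network, GSK-3 pathway, immediate early, NRF2, G2 and mitosis, glycolysis, lysosome and ribosomal protein lists changed sign at 3 h, and those of the extrinsic apoptosis, NRF2 and ribosomal protein lists at 6 h.

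In all, 10505 genes (66.3%) passed at 3 h against 0 h, 5201 higher and 5304 lower. Of these, 784 were at least 2-fold higher and 1678 at least 2-fold lower. The 3 libraries of each group did not overlap for 70.2% of genes, against 10% by chance. This division depended on the scaling: upper-quartile factors gave 3852 higher and 6854 lower (36.0% higher, median of all genes -0.17) and library size alone 3468 and 7451 (31.8%, median -0.22), against 49.5% and a median of -0.01 with TMM factors. Directions given here are relative to the TMM median. The largest rises among genes of at least 1 CPM included BHLHA15, a secretory cell transcription factor, 18.9-fold, CDKN1A, RNF11 8.14-fold and HSPA5, the endoplasmic reticulum chaperone BiP, 6.79-fold from 325 ± 2.07 CPM. The largest falls included BBC3, YPEL2 8.05-fold, NOL4L 7.19-fold and the sodium channel gene SCN4A 5.63-fold. The share of reads from mitochondrial RNA was 2.94% ± 0.154 at 0 h, 2.67% ± 0.145 at 3 h and 2.43% ± 0.179 at 6 h.

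**Figure D2:**
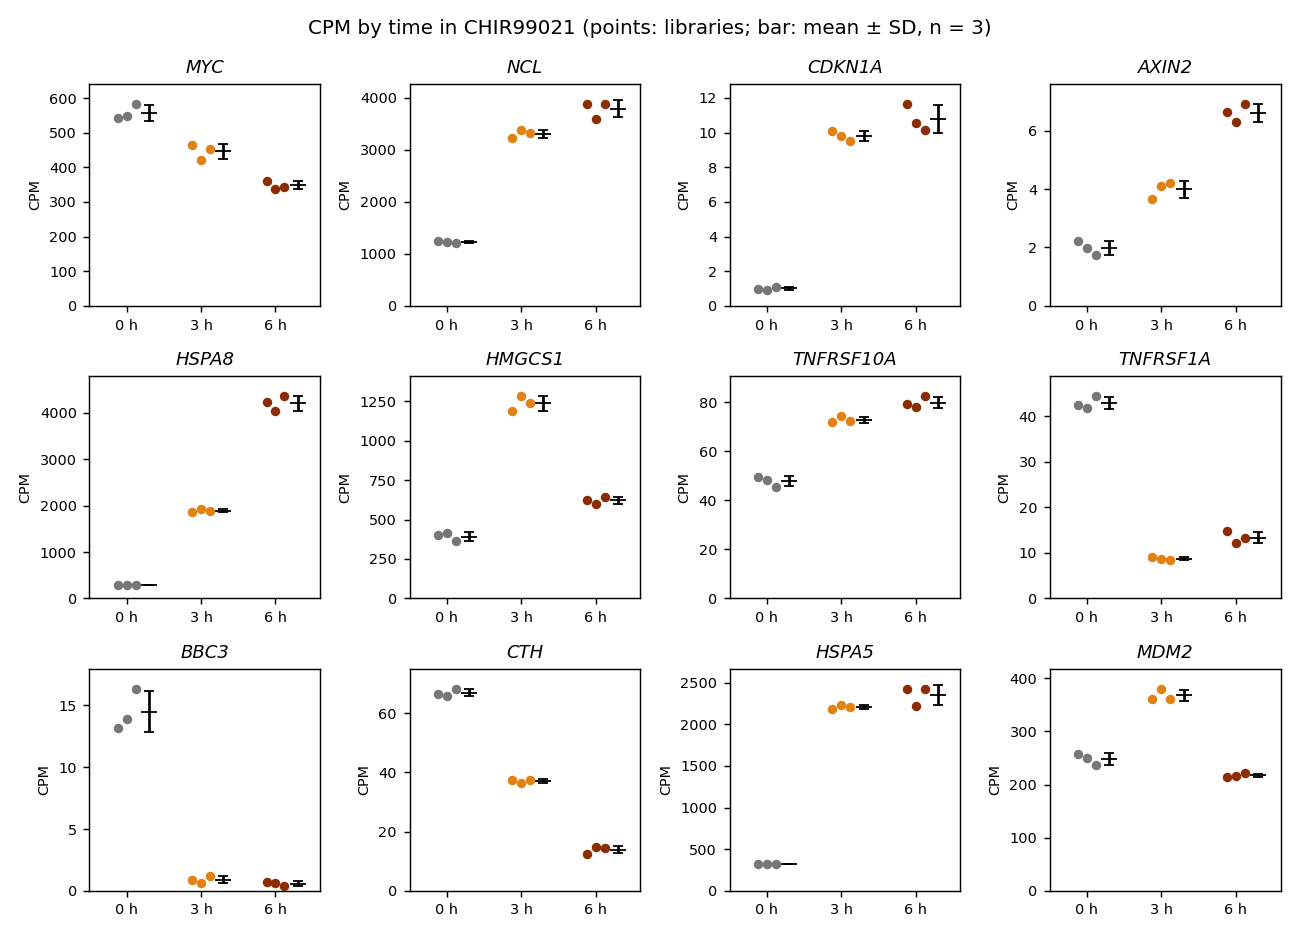
Normalised CPM (y axis, linear from 0) of 12 genes at 0, 3 and 6 h in CHIR99021 (x axis). Points are libraries and the bar is the mean ± SD of 3 libraries. MYC falls from 558 to 349 CPM and HSPA8 rises from 289 to 4208 CPM over 6 h, while HMGCS1 and MDM2 are highest at 3 h.

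At 6 h, MYC mRNA was lower still and the ribosome biogenesis genes stayed higher. MYC was at 349 ± 12 CPM, a log2 fold change of -0.68 (SE 0.052, edgeR adjusted p = 4.5e-08) against 0 h. All 29 ribosome biogenesis genes rose, by a median of 1.34 (2.53-fold; camera adjusted p = 7.85e-33; adjusted p = 0.0614 with an estimated correlation). NCL rose 3.08-fold, RRP12 4.91-fold and MYBBP1A, a nucleolar MYB-binding protein, 4.57-fold. Of the 31 genes of metabolism and translation, 26 rose and 3 fell, with a median of 0.80 (camera adjusted p = 1.64e-11; adjusted p = 0.133 with an estimated correlation). TFRC rose 5.17-fold, lactate dehydrogenase LDHA 2.29-fold and ODC1 2.06-fold. Of the 13 MYC-repressed genes, 10 fell and 2 rose, with a median of -1.0 (camera adjusted p = 0.000911; adjusted p = 0.133 with an estimated correlation). CDKN1B fell 2.86-fold, MXI1 3.82-fold and KLF6 2.19-fold, and CDKN1A rose 10.8-fold to 10.8 ± 0.790 CPM. In the MYC network list, 5 of 19 rose and 10 fell (camera adjusted p = 0.12). FBXW7 had a log2 fold change of 0.07 (SE 0.072, adjusted p = 0.404).

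The heat shock list had the highest median of the 26 tested lists at 6 h. All 15 genes rose, by a median of 2.23 (4.68-fold; camera adjusted p = 5.37e-41), and the call held with an estimated correlation (adjusted p = 0.0179). HSPA8 reached 4208 ± 162 CPM, a log2 fold change of 3.87 (SE 0.051, edgeR adjusted p = 6.31e-15). DNAJA1 rose 10.4-fold, DNAJB1 6.22-fold and HSPH1, a nucleotide exchange factor of HSP70, 5.21-fold. HSPA1B rose 21.4-fold and HSPA1A 17.5-fold, with the reservation on near-identical copies given above. Sterol genes were still higher, with 23 of 28 up and 2 down and a median of 0.48 (camera adjusted p = 6.79e-05; adjusted p = 0.266 with an estimated correlation), among them HMGCS1 1.59-fold and SQLE 1.57-fold. Of the 14 plasma cell genes, 8 rose and 5 fell (camera adjusted p = 0.011; adjusted p = 0.133 with an estimated correlation), with HSP90B1 5.61-fold and FKBP11 5.20-fold higher. Of the 24 G1/S genes, 16 rose and 3 fell (camera adjusted p = 0.0267; adjusted p = 0.622 with an estimated correlation, and 0.126 with scaling by library size alone). FEN1 rose 2.19-fold and E2F1, a transcription factor of the G1/S transition, fell 1.37-fold.

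ATF4 targets fell at 6 h, 23 of 26 with 2 higher, by a median of -0.78 (camera adjusted p = 7.48e-13; adjusted p = 0.0895 with an estimated correlation). CTH (ENSG00000116761), the cystathionine-cleaving enzyme of cysteine synthesis, fell from 66.9 ± 1.2 to 13.9 ± 1.2 CPM (log2 fold change -2.27, SE 0.062, edgeR adjusted p = 3.05e-12). PCK2 fell 3.65-fold, ATF3 3.89-fold and the glutathione-degrading enzyme CHAC1 3.3-fold, while HERPUD1 rose 1.93-fold. Of 21 p53 targets, 14 fell and 7 rose (camera adjusted p = 0.011; adjusted p = 0.133 with an estimated correlation), with TP53INP1 6.99-fold and SESN2 2.96-fold lower. Of 29 germinal centre B cell genes, 21 fell and 7 rose (camera adjusted p = 0.00117; adjusted p = 0.103 with an estimated correlation). BCL6 fell 1.96-fold, MEF2B 3.65-fold and CD38 1.66-fold, while MS4A1 rose 1.94-fold. Of 19 NF-kappaB targets, 12 fell and 4 rose (camera adjusted p = 0.0267; adjusted p = 0.282 with an estimated correlation; 0.0508 without 6 h replicate 10), with BCL3 4.38-fold and CD40 2.14-fold lower. Of 13 FOXO targets, 9 fell and 3 rose (camera adjusted p = 0.00908; adjusted p = 0.288 with an estimated correlation).

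The death receptor genes TNFRSF10A and TNFRSF10B kept opposite directions at 6 h. Of 25 extrinsic apoptosis genes, 12 rose and 9 fell (camera adjusted p = 0.46), with a median of 0.13 that turned to -0.11 with scaling by library size alone. TNFRSF10A reached 79.9 ± 2.27 CPM (log2 fold change 0.74, SE 0.049, edgeR adjusted p = 9.41e-09) and TNFRSF10B was at 40.3 ± 1.70 CPM (-0.48, SE 0.054, edgeR adjusted p = 2.21e-06). TNFRSF10D rose 3.29-fold, FAS fell 2.07-fold, TNFRSF1A 3.21-fold and CFLAR 1.24-fold. CASP8 rose 1.27-fold, with an adjusted p of 0.146 under scaling by library size alone. Of 17 BCL2 family and intrinsic genes, 11 fell and 4 rose (camera adjusted p = 0.0396; adjusted p = 0.133 with an estimated correlation). This list did not pass without 6 h replicate 10 (adjusted p = 0.0684) or with the GC and length trends removed (0.0837), with medians of -0.35 and -0.42 against -0.39 in the fit to all libraries. BBC3 fell 24.9-fold, BMF, also a BH3-only protein, 2.66-fold and APAF1 1.95-fold, while BCL2L11 rose 1.73-fold and CYCS 2.23-fold. MCL1 had a log2 fold change of 0.10 (SE 0.049, adjusted p = 0.0879), which reversed to -0.14 (adjusted p = 0.013) with library size alone and passed as a rise with the GC and length trends removed (0.0111).

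Beta-catenin/TCF targets still divided at 6 h, with 7 of 19 higher and 8 lower (camera adjusted p = 0.823, its sign opposite to the median of -0.40 and the mean of -0.01). AXIN2 reached 6.62 ± 0.309 CPM, 3.33-fold above 0 h, TCF7 was 2.39-fold and SGK1 3.18-fold higher, and LEF1 was 1.32-fold lower. Of 20 pathway components, 4 rose and 8 fell (adjusted p = 0.604). CTNNB1 rose 1.19-fold (adjusted p = 0.0571 with upper-quartile and 0.789 with library size scaling) and GSK3A 1.60-fold. GSK3B had a log2 fold change of -0.19 (SE 0.071, adjusted p = 0.0302), with overlapping libraries, and did not pass without untreated replicates 1 or 2 or any of the 6 h replicates (adjusted p = 0.0635 to 0.142). For all other genes named as rising or falling, the 3 libraries of each time lay apart. The other lists did not pass: higher and lower counts were 6 and 12 of 21 immediate early genes (0.15), 7 and 4 of 17 NRF2 targets (0.46), and 6 and 11 of 25 G2 and mitosis genes (5 and 11 when adjusted over the list alone; 0.646). They were 16 and 12 of 29 glycolysis and hypoxia genes (0.646; median 0.29, mean -0.08), 4 and 7 of 13 interferon genes (0.646) and 8 and 11 of 26 lysosome genes (0.477). For mitochondrial RNAs they were 2 and 3 of 13 (2 and 2 when adjusted over the list alone; 0.8), for ribosomal proteins 9 and 1 of 30 (3 and 1; 0.646) and for replication histones 1 and 11 of 14 (1 and 12; 0.112, and 0.0461 without untreated replicate 2). Where no second count is given, counts adjusted over the list alone were the same as those over all genes tested.

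**Figure D3:**
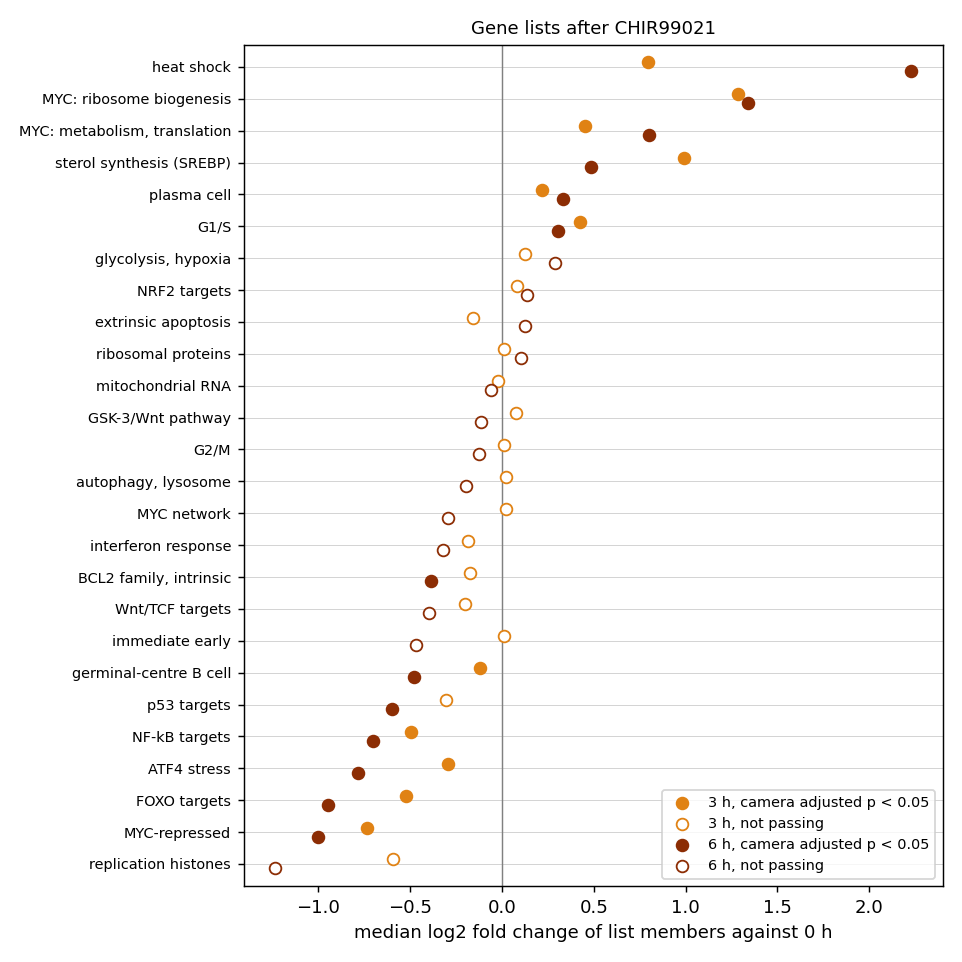
Median log2 fold change against 0 h (x axis) of the tested members of 26 gene lists (y axis) at 3 h and 6 h. Filled points pass camera with a preset correlation of 0.01 at an adjusted p under 0.05 and open points do not; the heat shock list has the highest median at 6 h (2.23).

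At 6 h against 0 h, 11213 genes (70.8%) passed, 5660 higher and 5553 lower, with 1020 at least 2-fold higher and 2061 at least 2-fold lower. Libraries did not overlap for 71.7% of genes, against 10% by chance. Upper-quartile scaling gave 4352 higher and 6736 lower (39.2% higher, median of all genes -0.13) and library size alone 3656 and 7504 (32.8%, median -0.22), against 50.5% and a median of 0.02 with TMM factors. The largest rises included AOX1, an aldehyde oxidase, 26.5-fold, the kinase LRRK2 23.2-fold, HSPA1B, and BHLHA15 18.3-fold. AOX1 and LRRK2 started at 0.190 ± 0.0421 and 0.118 ± 0.0586 CPM, so their folds are imprecise (log2 SE 0.204 and 0.259). The largest falls included BBC3, ABTB1 22.7-fold, SCN4A 21.9-fold, the small GTPase gene RAB37 14.8-fold, the protease FURIN 11.0-fold and YPEL3 10.4-fold.

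The comparison of 6 h with 3 h is also the test of whether the change from 0 h differed between the times. Heat shock genes were higher at 6 h than at 3 h, all 15 of them, by a median of 1.08 (2.11-fold; camera adjusted p = 7.94e-56), and the call held with an estimated correlation (adjusted p = 0.00633). HSPA8 rose 2.22-fold, HSPH1 2.78-fold and HSPA1B 5.17-fold. ATF4 targets were lower, 25 of 26 with 1 higher, by a median of -0.54 (camera adjusted p = 4.66e-21), which also held with an estimated correlation (adjusted p = 0.0399). CTH fell 2.67-fold, CHAC1 2.16-fold and PCK2 1.92-fold. Sterol genes fell from their 3 h level, 20 of 28 with 0 higher (21 and 1 when adjusted over the list alone), by a median of -0.32 (camera adjusted p = 7.85e-12; adjusted p = 0.0979 with an estimated correlation). HMGCS1 fell 1.99-fold, INSIG1 1.71-fold and SQLE 1.69-fold.

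Of the 29 ribosome biogenesis genes, 14 were higher and 2 lower at 6 h than at 3 h, with a median of 0.15 (camera adjusted p = 0.00922; adjusted p = 0.546 with an estimated correlation). MYBBP1A rose 1.67-fold and NOP56 fell 1.27-fold. Of the 31 genes of metabolism and translation, 16 rose and 4 fell (17 and 4 when adjusted over the list alone; camera adjusted p = 2.98e-07; adjusted p = 0.232 with an estimated correlation), and TFRC rose 1.92-fold. MYC fell 1.28-fold, with an adjusted p of 0.0724 against a minimum fold of 1.2. Of 13 MYC-repressed genes, 8 fell and 1 rose (8 and 2 when adjusted over the list alone), and of 19 MYC network genes 11 fell and 3 rose (11 and 4). Both lists had a camera adjusted p of 0.0302, which became adjusted p = 0.351 and 0.23 with an estimated correlation. The MYC-repressed list did not pass without 3 h replicate 7 (0.0547) or 6 h replicate 11 (0.0513). CDKN1A had a log2 fold change of 0.14 (SE 0.077, adjusted p = 0.168).

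Extrinsic apoptosis genes were higher at 6 h than at 3 h, 12 of 25 with 2 lower (13 and 2 when adjusted over the list alone; median 0.16, camera adjusted p = 0.0118; adjusted p = 0.341 with an estimated correlation). Of the 25 genes, 6 had fallen at 3 h and turned back, 3 had risen at 3 h and rose further, and 2 rose only after 3 h. TNFRSF1A, FAS and CFLAR were still lower at 6 h than at 0 h. Between 3 h and 6 h TNFRSF21, death receptor 6, rose 2.29-fold, TNFRSF10D 1.65-fold, TNFRSF1A 1.54-fold and CFLAR 1.25-fold, while RIPK1 fell 1.35-fold. TNFRSF10A rose 1.1-fold (adjusted p = 0.0414) but did not pass without untreated replicate 2, any of the 3 h replicates, or 6 h replicates 9 or 11 (adjusted p = 0.0584 to 0.139), nor with library size alone (0.0913), no filter (0.109) or GC and length trends removed (0.0764). TNFRSF10B had a log2 fold change of 0.04 (SE 0.055, adjusted p = 0.592). FAS rose 1.26-fold, lost without 3 h replicate 5 (0.0525), and CASP8 1.15-fold, lost without 3 h replicate 5 (0.0533) or 6 h replicate 11 (0.0566). Of 17 BCL2 family and intrinsic genes, 7 rose and 7 fell (7 and 8 when adjusted over the list alone; camera adjusted p = 0.42). BMF fell 2.17-fold, MCL1 1.24-fold and BCL2L11 1.1-fold, and the last did not pass without untreated replicate 2, any of the 3 h replicates, or 6 h replicates 9 or 11 (0.0504 to 0.109), nor with no filter (0.0874). BBC3 had a log2 fold change of -0.63 (SE 0.272, adjusted p = 0.0787).

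Of 21 p53 targets, 13 fell and 3 rose between 3 h and 6 h (14 and 3 when adjusted over the list alone; camera adjusted p = 2e-04; adjusted p = 0.0685 with an estimated correlation). TP53INP1 fell 2.44-fold and MDM2 1.69-fold. Of 21 immediate early genes, 12 fell and 2 rose (camera adjusted p = 0.00207; adjusted p = 0.351 with an estimated correlation), DUSP5 by 4.81-fold and SRF by 1.54-fold. Of 29 germinal centre B cell genes, 17 fell and 6 rose (18 and 8 when adjusted over the list alone; camera adjusted p = 0.00581; adjusted p = 0.151 with an estimated correlation), with CD38 1.49-fold lower and MS4A1 1.30-fold higher. Of 24 G1/S genes, 10 fell and 1 rose (camera adjusted p = 0.0441; adjusted p = 0.554 with an estimated correlation), with SLBP 1.38-fold and CDC6 1.26-fold lower. This list did not pass without 3 h replicate 7 (0.0642) or 6 h replicate 10 (0.0935).

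Among Wnt targets, 5 of 19 rose and 3 fell between 3 h and 6 h (5 and 4 when adjusted over the list alone; adjusted p = 0.831). AXIN2 rose 1.66-fold, TCF7 1.46-fold and SGK1 fell 1.44-fold. The TCF7 call was lost without 3 h replicate 7 (0.0919) or 6 h replicate 10 (0.0508). The lists that did not pass had higher and lower counts of 4 and 8 of 20 GSK-3 pathway genes (0.0873), 3 and 6 of 19 NF-kappaB targets (0.42), 4 and 4 of 17 NRF2 targets (5 and 4; 0.713) and 3 and 11 of 25 G2 and mitosis genes (4 and 11; 0.148). The GSK-3 pathway list passed without untreated replicate 3 (0.0462). Counts were 6 and 4 of 14 plasma cell genes (0.148), 1 and 7 of 13 FOXO targets (0.0873), 13 and 10 of 29 glycolysis and hypoxia genes (14 and 10; 0.651), 4 and 2 of 13 interferon genes (0.42) and 3 and 9 of 26 lysosome genes (0.148). They were 0 and 0 of 13 mitochondrial RNAs (0.42), 3 and 1 of 30 ribosomal proteins (1 and 1; 0.185) and 1 and 1 of 14 replication histones (0 and 1; 0.42). A second count is the one adjusted over the list alone. Median and test differed in sign for the Wnt target (-0.01), plasma cell (-0.02) and interferon (-0.02) lists, and mean and median for the NRF2 (-0.04 and 0.04) and glycolysis (-0.02 and 0.12) lists.

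Between 3 h and 6 h, 6871 genes (43.4%) passed, 3402 higher and 3469 lower, with 264 at least 2-fold higher and 344 at least 2-fold lower. Libraries did not overlap for 55.2% of genes, against 10% by chance. Against a minimum fold of 1.2, 1136 were higher and 1368 lower. The largest rises included AOX1 6.88-fold, the Fc receptor-like gene FCRL5 5.47-fold and SCML4 3.97-fold, the latter pair with log2 fold changes at 3 h of -0.17 (SE 0.241, adjusted p = 0.546) and 0.24 (SE 0.149, adjusted p = 0.178). The largest falls included RAB37 6.87-fold, FURIN 5.83-fold, ABTB1 4.96-fold and YPEL3 4.43-fold.

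**Figure D4:**
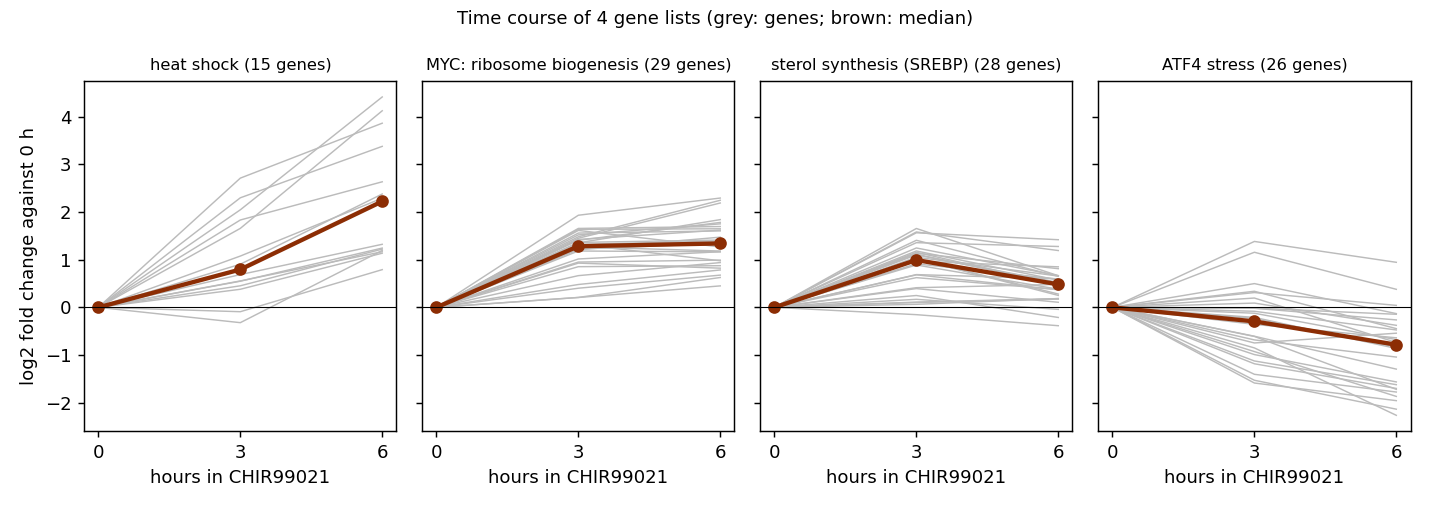
Log2 fold change against 0 h (y axis) by hours in CHIR99021 (x axis) for the members of 4 gene lists, with grey lines for genes and the brown line for the median. The heat shock median climbs from 0.80 to 2.23, ribosome biogenesis holds near 1.28 and 1.34, sterol synthesis peaks at 0.99 and ATF4 targets decline to -0.78.

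The time courses of single genes fell into classes set by the 3 comparisons. A change that passed at both times in the same direction, and did not pass between 3 h and 6 h, was seen in 2159 genes for rises and 2482 for falls. Another 1381 rose and 1353 fell at 3 h and moved further the same way by 6 h, a class not fixed beforehand. A rise at 3 h that turned back by 6 h was seen in 1382 genes. Of these 800 were still higher than at 0 h, 456 did not pass against 0 h and 126 were lower. A fall at 3 h that turned back was seen in 1148 genes, and 728 genes rose and 646 fell only between 3 h and 6 h and against 0 h. Of the 28 sterol genes 19 were in the rise that turned back, against 8.72% of all genes. Of the 15 heat shock genes 13 rose progressively, against 8.71%, and of the 26 ATF4 targets 15 fell progressively, against 8.54%.

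Genes that rose at both times against 0 h numbered 4340, where independent lists would share 1858, and 4396 fell at both, where 1859 would be shared. Another 257 passed in opposite directions. Simulated groups with no effect, compared with the same simulated untreated libraries, gave at most 1 gene that rose and 2 that fell at both times in edgeR (60 to 106 and 52 to 92 at an unadjusted p under 0.05, where 4508 and 4561 were observed). Across genes, which are not independent replicates, the log2 fold changes at 3 h and 6 h correlated with a Pearson's r of 0.85, and 85% had the same sign. The simulated groups gave a mean r of 0.47 (0.427 to 0.501 in 100 simulations) and 66.2% with the same sign. The covariance was 0.56 against a simulated 0.0161, a difference of 0.55. The count for independent lists left out the shared controls, and the simulated groups left out the effects. With 3 untreated libraries the controls could not be split into sets of at least 2, so part of the excess in shared genes over independent lists may come from the shared controls.

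At 3 h against 0 h, 11 lists passed camera, 6 higher and 5 lower, at 6 h 13 did, 6 higher and 7 lower, and between 3 h and 6 h 12 did, 4 higher and 8 lower. With an estimated correlation 0, 1 and 2 did, namely heat shock in both comparisons of 6 h and ATF4 targets at 6 h against 3 h. Without untreated replicate 2, 7 lists passed at 3 h. Markers of other cell types were near absent. Of 14 T and NK cell genes 12 stayed below 1 CPM in every library, the exceptions being LCK and ZAP70, which B cell lines can express, at up to 157 and 16.4 CPM. Of 13 myeloid genes 12 stayed below 1 CPM, the exception being AIF1 at up to 3.60 CPM, as did all 15 epithelial and fibroblast genes. A count of 0 allows up to 0.0567 to 0.0647 CPM in a library, for counting error only.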

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

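The 3 tests of the heat shock pattern, the test of background reads and the removal of GC and length trends were chosen only after the results they concern were seen.

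For 78 of 93 genes examined the change from 0 h differed between 3 h and 6 h, by the edgeR test of the difference itself at an adjusted p under 0.05. Of these 33 were higher and 45 lower at 6 h. Some of these genes were named for a small p or a large change between 3 h and 6 h, so this share is higher by construction, and 43.4% of all genes tested differed between these times. MDM2 and TNFRSF21 passed against 0 h in opposite directions at the 2 times. Among genes of the MYC network and of MYC targets, these log2 fold changes at 6 h against 3 h were -0.36 for MYC, -0.34 for MXI1, -0.48 for MXD3, -0.31 for USP36, 0.20 for NCL, -0.35 for NOP56, 0.36 for RRP12, 0.74 for MYBBP1A, 0.94 for TFRC, 0.30 for ODC1, 0.49 for LDHA, -0.32 for CDKN1B, 0.41 for GADD45A, -0.40 for KLF6, -0.23 for CCNG2 and -0.31 for FBXW7. Among genes of the GSK-3 and beta-catenin lists they were 0.73 for AXIN2, -0.18 for LEF1, 0.55 for TCF7, 0.37 for GSK3A, -0.33 for GSK3B and -0.53 for SGK1. Among apoptosis genes they were 0.13 for TNFRSF10A, 0.33 for FAS, 0.32 for CFLAR, 0.20 for CASP8, 0.62 for TNFRSF1A, 0.72 for TNFRSF10D, -0.43 for RIPK1, -0.16 for XIAP, 1.19 for TNFRSF21, -0.31 for MCL1, -0.14 for BCL2L11, 0.40 for CYCS, -1.12 for BMF and 0.24 for APAF1. Among sterol genes they were -0.99 for HMGCS1, -0.76 for SQLE and -0.77 for INSIG1. Among heat shock genes and a pseudogene they were 1.15 for HSPA8, 2.37 for HSPA1B, 2.47 for HSPA1A, 1.08 for DNAJA1, 0.80 for DNAJB1, 1.47 for HSPH1 and 1.11 for HSPA8P7. Among ATF4 and p53 targets they were -1.42 for CTH, -0.94 for PCK2, -1.11 for CHAC1, -0.37 for ATF3, -0.44 for HERPUD1, -0.57 for SESN2, -0.76 for MDM2 and -1.29 for TP53INP1. Among cell cycle, immediate early and NF-kappaB genes they were -0.34 for CDC6, -0.46 for SLBP, -0.39 for E2F1, -2.27 for DUSP5, -0.62 for SRF, -0.16 for CD40 and -0.14 for CD83. Among germinal centre B cell and plasma cell genes they were -0.22 for BCL6, -0.74 for MEF2B, 0.38 for MS4A1, -0.58 for CD38, 0.48 for HSP90B1 and 0.96 for FKBP11. Among genes named for the size of their change they were -1.96 for SCN4A, -2.78 for RAB37, -2.15 for YPEL3, -0.53 for NOL4L, 1.79 for LRRK2, 2.78 for AOX1, -0.54 for RNF11, -2.54 for FURIN, 2.45 for FCRL5, 1.99 for SCML4 and -2.31 for ABTB1.

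For 12 lists the change also differed between the times by camera at the preset correlation. Their median log2 fold changes at 6 h against 3 h were 0.15 for ribosome biogenesis, 0.30 for MYC-activated metabolism and translation, -0.23 for MYC-repressed genes, -0.29 for the MYC network, 0.16 for extrinsic apoptosis, -0.27 for p53 targets, -0.42 for immediate early genes, -0.54 for ATF4 targets, -0.32 for sterol synthesis, -0.11 for G1/S genes, -0.19 for germinal centre B cell genes and 1.08 for heat shock. With an estimated correlation the heat shock (adjusted p = 0.00633) and ATF4 (0.0399) lists passed and the other lists did not.

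Heat shock genes were higher at 6 h than at 0 h, all 15 of them. The 8 members without a counted pseudogene of their own name had a median log2 fold change of 1.81 (95% bootstrap interval 1.2 to 4.13, over members) and a lowest of 1.14. HSPA8 pseudogenes held 2.52%, 2.52% and 2.41% as many reads as HSPA8 at 0 h, 3 h and 6 h. These values argue against reads shared with pseudogenes of a member's own name. Pseudogenes under other names were not looked for, and the 8 include the near-identical HSPA1A and HSPA1B, so other shared reads stay open. The first test of scaling left it open, because the median under the least favourable of 4 scalings was 1.99 with an interval of 0.96 to 3.14 that reached below its bound of 1. It was replaced after that outcome by the lowest member under any of the scalings, since scaling moves all genes alike. This was HSPB1 at 0.55 (SE 0.093, edgeR adjusted p = 0.000249), with 15 of 15 members passing. All 15 had already passed with TMM factors, and the medians under the 4 scalings ran from 1.99 to 2.225. The replacement therefore describes these scalings and is not an independent test. Handling or time in culture, for which there were 0 untreated libraries at 3 h or 6 h, cannot be told apart from the inhibitor, so it stays open as a candidate explanation beside an effect of CHIR99021. Levels here are shares of all reads, so levels per cell were not measured.

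At 3 h abundant genes tended to be higher and rare genes lower, with a median log2 fold change of -0.39 at up to 0.5 CPM and 0.24 between 100 and 1000 CPM (Spearman's rho 0.345 across genes, and genes are not independent replicates). With GC and length trends removed rho was 0.344 (95% interval 0.33 to 0.359), against 0.346 before in the same 97.2% of genes, while rho with GC content went from -0.162 to -0.017. Among the 9029 genes of at least 10 CPM rho was 0.264 (0.246 to 0.285). Background reads that affect rare genes alone do not account for the trend in those genes, but a part in rarer genes stays open. Mean CPM was taken over all 9 libraries, so a gene that rose in the treated libraries also gained in mean CPM. Part of each rho may come from this coupling, which was not separated. An effect of the treatment stays open, as does one of time, and neither was tested.

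Ribosome biogenesis genes were higher at 3 h while MYC mRNA was lower. The abundance trend does not account for it, since the list median of 1.28 (95% bootstrap interval 1.18 to 1.41, over members) lay above the highest of 10000 random lists matched on mean CPM, 0.58. GC and length do not either, since the median was 1.23 (1.1 to 1.5) with those trends removed. A higher level of MYC protein, as the series title names, may account for the pattern, as may other targets of the inhibitor. Neither was measured, so both remain hypotheses. Handling or time in culture also stays open, since no untreated library was kept for 3 h.

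Other splits of the libraries were counted. For 3 h against 0 h the real split gave 10505 genes and the highest of the others 0, for 6 h against 0 h 11213 and 0, and for 6 h against 3 h 6871 and 0, so 1 of 10 splits gave as many in each, and 10 splits are too few for a share under 0.05. For the 3 times together, 1 of 100 splits drawn from 280 gave as many as the real 12319, with 8583 the highest of the others. This is a share under 0.05 and the smallest that 100 splits can give. The sampled splits that kept the untreated libraries together and mixed 3 h with 6 h gave 8176 to 8583 genes, so this count rests largely on untreated against treated libraries.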

How the results depend on the processing

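Each choice was changed alone, except that the filter was applied anew where a library was left out (16044 to 16196 genes tested, against 15847) or only the compared groups were used (15073 to 15612), and that DESeq2 used its own size factors. With scaling by library size alone, 3656 genes were higher at 6 h against 0 h, and the log2 fold changes reversed for MCL1 (-0.137), RPL23 (-0.015) and RPS14 (-0.054) at 6 h and for RPL6 at 3 h (-0.059, and -0.011 with upper-quartile factors); these factors shift the median of all genes, as given with the counts. Against a minimum fold of 1.2, 3453 genes were higher at 3 h against 0 h, and 1136 were higher and 1368 lower at 6 h against 3 h, as a stricter threshold brings. At an adjusted p under 0.01, 743 genes had a fall at 3 h that turned back, for the same reason. With an estimated correlation 0, 1 and 2 lists passed at 3 h against 0 h, 6 h against 0 h and 6 h against 3 h, and with fry, which does not compare a list with other genes, 17, 22 and 20 did. Leaving out each library in turn, the lists that passed at 3 h numbered 7 to 11, with 7 without untreated replicate 2; the cause was not tested. At 6 h they numbered 11 to 14 and between 3 h and 6 h 10 to 13. Genes higher at 3 h ranged from 4885 to 5332 and lower from 4862 to 5443, and at 6 h from 5297 to 5780 and 5304 to 5798. Between 3 h and 6 h they ranged from 2813 to 4008 and 2926 to 4095, and for any difference among the 3 times from 11860 to 12765. The correlation of the 3 h and 6 h changes across genes was 0.86 by Spearman's rho and 0.85 without each untreated replicate. Of 7231 values of named genes under alternatives, 7093 kept their direction and side of the threshold, 119 lost the threshold, 14 gained it and 5 reversed. Of the 119, 53 came from the minimum fold of 1.2. DESeq2, limma-voom and DESeq2 size factors kept 381 of 381. No paired analysis was possible because the replicate numbers, 1 to 3, 5 to 7 and 9 to 11, are not shared between the times. Small changes are limited by the 3 libraries per group, to an extent not measured at the share of changed genes seen here. The simulation found 14% of 1.2-fold changes at 3 h, but with far fewer changed genes than the 66.3% that passed in the data. Fold changes of genes near the level a count of 0 allows, such as DUSP5, are imprecise.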

Other observations

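The following lists were chosen after seeing the data, so their tests describe these libraries and are not independent evidence. Their camera p-values were adjusted only over the added lists with at least 5 tested members, not together with the 26 fixed lists. Adjustment over so few lists is milder, so these adjusted p-values cannot be set beside those of the fixed lists. Genes of protein folding, translocation and degradation at the endoplasmic reticulum, with the transcription factor XBP1, were higher, 24 of 26 at 3 h with 2 lower (median log2 fold change 1.24, camera adjusted p = 4.42e-30; adjusted p = 0.00665 with an estimated correlation) and 24 at 6 h with 1 lower (median 1.62, camera adjusted p = 1.18e-36; adjusted p = 0.00588 with an estimated correlation). Of the 26 members 2 are also in the fixed lists. HSPA5, the chaperone BiP, rose from 325 ± 2.07 CPM to 2205 ± 21.9 CPM at 3 h and 2354 ± 121 CPM at 6 h. The lectin chaperone CALR rose 2.85-fold and 5.58-fold, and the disulfide isomerase PDIA4 2.73-fold and 5.07-fold. DNAJB9, a co-chaperone of BiP, rose 4.72-fold at 3 h and 2.83-fold at 6 h. Between 3 h and 6 h 17 members rose and 5 fell (camera adjusted p = 1.25e-08; adjusted p = 0.118 with an estimated correlation).

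Of 4 tested Yippee-like genes, 4 fell at 3 h (median log2 fold change -1.18) and at 6 h (median -2.65), too few for a list test. YPEL5 fell 2.03-fold at 3 h and 5.23-fold at 6 h, and YPEL1 2.20-fold and 4.95-fold. Of 9 circadian clock and PAR bZIP genes, 5 rose and 2 fell at 3 h (camera adjusted p = 0.0513) and 5 rose and 3 fell at 6 h (adjusted p = 0.657). The clock gene PER2 rose 2.42-fold at 3 h and 1.5-fold at 6 h, and the PAR factor TEF 2.92-fold and 2.38-fold, while DBP, also a PAR factor, fell 3.73-fold and 2.93-fold. Between 3 h and 6 h 4 fell and 1 rose (camera adjusted p = 0.0353; adjusted p = 0.186 with an estimated correlation). Of 20 cytoplasmic tRNA synthetases, 11 rose and 4 fell at 3 h (adjusted p = 0.194), 6 rose and 8 fell at 6 h (adjusted p = 0.678), and 6 rose and 9 fell between them (adjusted p = 0.147), and 3 of them are in the fixed lists.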
